A study of Mus musculus with 32 samples.

How the data were processed

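The samples were left ventricles of mice, a series of 32 RNA-seq libraries. The series asked what inhibition of the kinase CAMK2D does in mice with altered Rbm20, the gene of the splicing regulator RBM20. RNA was taken up in TRIzol and libraries were made with a SMART-Seq total RNA kit for very small inputs, per the labels' protocols. Reads were trimmed with Trimmomatic and the genome build was mm10/GRCm38, per the submitters' processing notes. The aligner, the program that counted reads and its gene annotation are not given in the sources used here.

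The authors deposited 2 tables. The first, as deposited by the authors, holds expected counts, that is, each estimated count of reads per gene need not be whole, for 20 libraries of 4 genotype groups, and 71.6% of its values above 0 were whole. These values were rounded to whole numbers before testing. The second table that the authors deposited holds whole counts per gene for 12 libraries of 4 groups that received hesperadin or its vehicle, by gene symbol only and without mitochondrially encoded genes. Neither table was scaled by library size. Each was normalized separately, and groups were tested only within a table. CPM of both tables were set against each other only across genes, in a check of transcript length. Every column matched 1 library by name, and 0 columns were left over.

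Total counts per library lay between 21799975 and 23635833 in the knockout table and between 15142594 and 23427216 in the hesperadin table. Mitochondrially encoded genes took 42.65 to 52.83% of the counts in the knockout table. The 10 most abundant genes took 42.29 to 51.51% of the counts there and 26.9 to 28.77% in the hesperadin table. Annotated ribosomal RNA genes took 0.446 to 1.26% and 1.54 to 3.31%, in the same order. Mitochondrially encoded ribosomal RNA could count only in the knockout table, so these ranges cover unlike sets of genes and cannot be compared. No 2 libraries held identical values, and the chi-square per gene between libraries of a group was at least 7.82, far above sampling noise, so every library counts as 1 replicate. The labels do not say that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. Reads carry no molecular identifiers, and a floor of 3 counts over a group, used where a group is at 0, covers counting error only.

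Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, which left 14077 genes of the knockout table and 14579 of the hesperadin table. Libraries were scaled by TMM, and a robust quasi-likelihood fit was made on all groups of a table, which then shared 1 estimate of the spread, with 16 and 8 residual degrees of freedom and a common biological coefficient of variation of 0.14 and 0.149. Called genes had a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The knockout comparisons were Rbm20 knockout against wild type, the Camk2d knockout label against wild type, the double knockout label against each of the other groups, and the interaction, which is the change with the Camk2d knockout label in Rbm20 knockouts minus that in mice with Rbm20. The hesperadin comparisons were knock-in against wild type on vehicle, each dose and the mean of both doses against vehicle in knock-in mice, and the higher against the lower dose. Errors after a log2 fold change are standard errors of the fit, and those after a level in CPM (counts scaled by library size) are standard deviations. Where several symbols matched one name (120 duplicated symbols in the knockout table), genes were told apart by Ensembl identifier.

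The text names genes by this rule: Rbm20 and Camk2d, the 10 called genes with the largest rises and the 10 with the largest falls that reached 1 CPM in a group and whose groups did not overlap, up to 4 members with the smallest p of each list that passed its test or had at least 3 called members, and all called genes where 16 or fewer were called. Non-overlap was not asked of the interaction. Symbols of predicted genes, clones and pseudogenes were passed over. Fewer genes may be named, in that order, and a gene outside the rule is said to be so.

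Gene lists were 31 sets: fetal and stress, extracellular matrix, RBM20 splicing target, sarcomere, calcium handling, cardiac ion channel, calcium/calmodulin kinase, nuclear OXPHOS (oxidative phosphorylation), mitochondrially encoded, fatty acid oxidation, glycolysis, inflammatory cytokine, immediate early, integrated stress response, ER chaperone, interferon response, mitotic and Aurora kinase, p53 target, heat shock, circadian clock, and AhR and NRF2 target genes, and markers of fibroblasts, endothelium, mural cells, macrophages, lymphocytes and neutrophils, atrium, erythroid cells, adipocytes, mesothelium and Schwann cells. They were written from textbook knowledge and chosen on none of these samples. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry (limma 3.58.1). Counts of called members were also adjusted over the list alone. Measured members were found for 30 lists in the knockout set and for 29 in the hesperadin set. Bulk tissue was measured, so marker lists describe levels and not numbers of cells, and counts per gene cannot measure splicing.

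The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, voom with quality weights, leaving out mitochondrially encoded and ribosomal RNA genes, the replicate number as a block, only the 2 groups compared, Xist as a covariate where libraries fell apart by it, and leaving out each library in turn. Chosen after the data were seen were a clock gene covariate, leaving out libraries with Myl7 over 10 CPM, and leaving out genes within 20 Mb of Camk2d or Rbm20. Comparisons that share libraries were set beside 20 simulations of unchanged groups. The fit was tested on simulated counts with 200 genes changed by known folds: for the higher hesperadin dose against vehicle it recovered 44.8% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.9% of those changed 4-fold, out of 14338 genes tested. For the double knockout label against Rbm20 knockout, with 13824 genes tested, these shares were 71.6, 83.6 and 97%. Gene positions come from GENCODE M21 on GRCm38.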

Results

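Gene expression was measured by RNA-seq in the left ventricle of mice from 2 models with altered Rbm20. RBM20 is an RNA-binding protein that regulates splicing of titin and other heart transcripts, and CAMK2D is the main cardiac isoform of calcium/calmodulin-dependent kinase II. The knockout set held 5 libraries each of wild type, homozygous Rbm20 knockout, homozygous Camk2d knockout and the double knockout. The hesperadin set held 3 libraries each of wild type on DMSO, heterozygous Rbm20 R636Q knock-in mice on DMSO, and knock-in mice on hesperadin at 2.5 or 5 ug/mg. Hesperadin inhibits CaM kinase II and also Aurora B kinase, and DMSO is its vehicle. The series has no wild-type mice on hesperadin. Each knockout library held 21799975 to 23635833 counts and each hesperadin library 15142594 to 23427216.

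Rbm20 (chromosome 19, 53677306 to 53867080, plus strand, GRCm38) followed its label. It stood at 76.7 ± 8.51 CPM in wild type (SD, n = 5) and at 22.9 ± 1.12 CPM in the Rbm20 knockout (n = 5), a log2 fold change of -1.74 ± 0.091 with an edgeR adjusted p of 2.7e-11. It was at 79.6 ± 5.58 CPM in libraries labelled Camk2d knockout and at 23 ± 3.65 CPM in those labelled double knockout. Camk2d (chromosome 3, 126596302 to 126846326, plus strand) did not follow its label as clearly. It was at 98.3 ± 3.79 CPM in wild type, 112 ± 4.37 in the Rbm20 knockout, 86.8 ± 8.16 in libraries labelled Camk2d knockout and 92.7 ± 11.5 in those labelled double knockout. Against wild type its log2 fold change was -0.18 ± 0.074 with the Camk2d knockout label (adjusted p 0.226). Between the double knockout label and Rbm20 knockout it was -0.27 ± 0.074 (adjusted p 0.0448), a call that ended without any 1 of 8 single libraries, with adjusted p up to 0.116 without double knockout library 3. A count over the whole gene checks such a label only where it covers the deleted part, which the labels do not give. The directions below that involve Camk2d therefore rest on the labels. The numbers in the deposited library names were all lower in groups labelled Camk2d or double knockout than in wild type and Rbm20 knockout. What these numbers stand for is not given, and the label cannot be told apart from what they follow. In the hesperadin set Rbm20 stood between 550 ± 9.24 and 593 ± 39.4 CPM in the 4 groups and Camk2d between 257 ± 18 and 269 ± 12.6 CPM (n = 3 each), with no call for either gene.

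**Figure D1:**
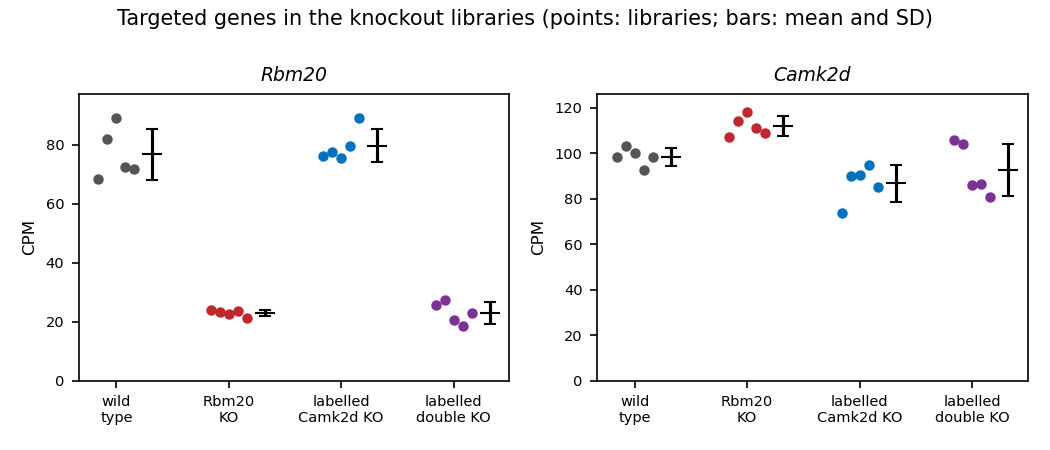
CPM of Rbm20 and Camk2d (vertical axes) in each of the 20 knockout libraries, by group. Points are libraries and bars give mean and SD. Rbm20 lay between 21.2 and 24 CPM in the Rbm20 knockout and between 68.2 and 89 in wild type, while Camk2d in libraries labelled Camk2d knockout (73.6 to 94.9 CPM) overlapped with wild type (92.4 to 103).

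The Rbm20 knockout heart had more transcript of fetal and stress genes. Most genes of the fatty acid oxidation and nuclear OXPHOS lists were called lower, although the tests of these lists did not hold with an estimated correlation (adjusted p = 0.233 and 0.266). Of 14077 genes tested, 797 rose and 1115 fell against wild type by edgeR, and 152 and 164 of these changed at least 2-fold. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079), rose from 139 ± 27 to 1101 ± 483 CPM (n = 5 each), a log2 fold change of 2.98 ± 0.34. Larger rises were those of Syndig1 (4.05 ± 0.46), the ganglioside sialyltransferase St8sia1 (3.82 ± 0.27) and the phosphatase Dusp26 (3.31 ± 0.43). Endothelin 3 (Edn3, 2.92), the transcription factor Tbx15 (2.82), the skeletal muscle calsequestrin Casq1 (2.61), the chloride channel Clcnkb (2.51), Fgf6 (2.48) and Gpr75 (2.47) completed the 10 largest. Cyfip2, a subunit of the actin-regulating WAVE complex (chromosome 11, 46193850 to 46312859, minus strand), fell from 121 ± 24 to 3.65 ± 1.08 CPM, a log2 fold change of -5.05 ± 0.24. Wild-type library 5 held 78.8 CPM of it and the other wild-type libraries 127 to 139. The liver-type aldolase Aldob followed with -4.62 ± 0.44, at 2.04 ± 0.23 CPM in wild type, and then Ptchd3 (-4.50), the Nogo receptor Rtn4r (-2.93), Ifi205 (-2.77), epidermal growth factor Egf (-2.60), Lgr6 (-2.37), metallothionein 2 (Mt2, -2.31), Tchh (-2.29) and angiotensinogen Agt (-2.15). Tchh was no longer called without Rbm20 knockout library 5 (adjusted p 0.0569).

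Of 15 fetal and stress genes, which are raised in stressed ventricle, 9 rose and 0 fell (11 up and 1 down adjusted over the list alone). The list passed camera (adjusted p 2.82e-13) and held with an estimated correlation (adjusted p = 0.0346). Beside this, the atrial gene Myl7 was at 9.16, 2.4 and 7.07 CPM in Rbm20 knockout libraries 2, 3 and 5. It was at 11.1 CPM in wild-type library 5, and at or below 0.147 CPM in the other libraries of both groups. Fhl1 rose from 77.8 ± 9.64 to 166 ± 31.8 CPM (log2 fold change 1.10), Xirp2 to 908 ± 262 CPM (1.23), and Csrp3 by 0.49 on the log2 scale. Of 27 extracellular matrix genes 7 rose (11 adjusted over the list alone), among them Tgfb2 (1.04), Loxl1 (0.62), biglycan Bgn (0.75) and Cilp (2.41). That list passed camera (adjusted p 1.8e-06) but not with an estimated correlation (adjusted p = 0.597). Of 12 fibroblast markers 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p 0.0258, 0.803 with an estimated correlation), with Islr at 0.72, Lum at 0.75, Pdgfra at 0.34 and Dpep1 at -0.53. Of 23 sarcomere genes 6 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p 0.0419, 0.83 with an estimated correlation). Myh7, the slow myosin heavy chain, rose from 888 ± 414 to 2935 ± 516 CPM (1.72), the titin cap protein Tcap rose by 0.65 on the log2 scale, and obscurin Obscn fell by 0.37 on the log2 scale. Cilp, Lum, Pdgfra and Dpep1 lost their calls without single libraries, with adjusted p up to 0.081 for Dpep1 without Rbm20 knockout library 5.

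Among fuel genes, 3 lists leaned down in the Rbm20 knockout by camera, and none of them passed with an estimated correlation. Of 21 fatty acid oxidation genes 17 fell and 0 rose (18 and 0 adjusted over the list alone), led by the dienoyl-CoA reductase Decr1 (-0.58 ± 0.089), the electron transfer flavoprotein subunits Etfa (-0.36) and Etfb (-0.46) and Etfdh (-0.41). Of 28 nuclear OXPHOS genes, which encode respiratory chain subunits, 21 fell and 0 rose (24 and 0 adjusted over the list alone), among them Ndufs3 (-0.33), Ndufs2 (-0.36), Atp5b (-0.32) and Ndufa9 (-0.31). Of 17 glycolysis genes 7 fell (10 adjusted over the list alone), led by hexokinase Hk1 (-0.59) and the glucose transporter Slc2a4 (-0.35). The adjusted p by camera was 2.6e-15, 2.01e-12 and 0.000109 for these lists. With an estimated correlation the adjusted p = 0.233, 0.266 and 0.412, so that none of the 3 calls held. None of the 13 mitochondrially encoded genes was called (camera adjusted p 0.411, fry 0.536).

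Among 21 cardiac ion channel genes 6 fell and 2 rose (7 and 2 adjusted over the list alone, camera adjusted p 0.312). The sodium channel subunit Scn4b fell by 2.14 on the log2 scale, the pacemaker channel Hcn2 from 14.6 ± 1.71 to 5.74 ± 2.21 CPM (-1.35), with 9.58 CPM in Rbm20 knockout library 1 and 3.92 to 5.17 in the others, and the potassium channel partner Kcnip2 by 0.60 on the log2 scale, while the T-type calcium channel Cacna1g rose (1.56). The 23 RBM20 splicing targets went both ways, with 4 up and 6 down (5 and 6 adjusted over the list alone, camera adjusted p 0.993), as in Rtn4 (0.54), Obscn (-0.37), Mlip (-0.33) and Lmo7 (-0.38). These values are totals per gene and do not show isoforms. Of 19 calcium handling genes 1 rose, Casq1, and 3 fell (the same adjusted over the list alone, camera adjusted p 0.537): the ryanodine receptor Ryr2 (-0.39), the sodium-calcium exchanger Slc8a1 (-0.31) and Hrc (-0.26, lost without any 1 of 5 libraries, adjusted p up to 0.121 without Rbm20 knockout library 5). Among 11 calcium/calmodulin kinase genes 1 rose and 1 fell (camera adjusted p 0.537).

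Lists of clock, blood and stress response genes had few calls. Of 16 circadian clock genes 3 rose (4 adjusted over the list alone), namely Bhlhe41 (0.54), Nr1d1 (0.83) and Dbp (0.50, lost without Rbm20 knockout library 1 or wild-type library 2, adjusted p up to 0.0701). The list passed camera (adjusted p 0.0291) but not with an estimated correlation (adjusted p = 0.266). Of 6 erythroid markers 1 fell, Hba-a2 (4 adjusted over the list alone, camera adjusted p 0.011, 0.542 with an estimated correlation). Of 15 interferon response genes 1 rose (0 adjusted over the list alone), Rtp4 (0.80, lost without any 1 of 7 libraries, adjusted p up to 0.145 without Rbm20 knockout library 5), with a camera adjusted p of 0.0369 that became adjusted p = 0.83 with an estimated correlation. Of 12 AhR and NRF2 target genes 1 fell, Gsta4 (-0.43; camera adjusted p 0.0419, 0.597 with an estimated correlation). Of 14 p53 target genes 3 fell and 0 rose (3 and 2 adjusted over the list alone, camera adjusted p 0.537), which were Fas (-0.69), Ccng1 (-0.31) and the cell cycle inhibitor Cdkn1a (-0.78). The call of Ccng1 ended without Rbm20 knockout library 3 (adjusted p 0.0628) and that of Cdkn1a without any 1 of 8 libraries, with adjusted p up to 0.138 without wild-type library 2.

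The remaining lists did not pass camera in this comparison. Camera gave an adjusted p of 0.587 for 7 inflammatory cytokine genes with 0 calls, 0.579 for 17 immediate early genes with 1 fall, 0.794 for 15 integrated stress response genes with 1 fall, 0.993 for 13 ER chaperone genes with 1 rise and 1 fall, and 0.993 for 19 mitotic and Aurora kinase genes with 1 fall. It gave 0.814 for 13 heat shock genes and 0.537 for 12 endothelial markers, with 0 calls in each, 0.675 for 10 mural cell markers with 1 rise, and 0.603 for 13 macrophage markers with 1 rise and 1 fall. The value was 0.118 for 7 atrial markers with 1 rise, Nppa, 0.993 for 1 adipocyte marker and 0.587 for 2 mesothelial markers with 0 calls, and 0.312 for 4 Schwann cell markers with 1 fall. Lymphocyte and neutrophil markers had no member measured in the knockout set, and the 1 measured in the hesperadin set was not called in R636Q hearts (camera adjusted p 0.897).

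**Figure D2:**
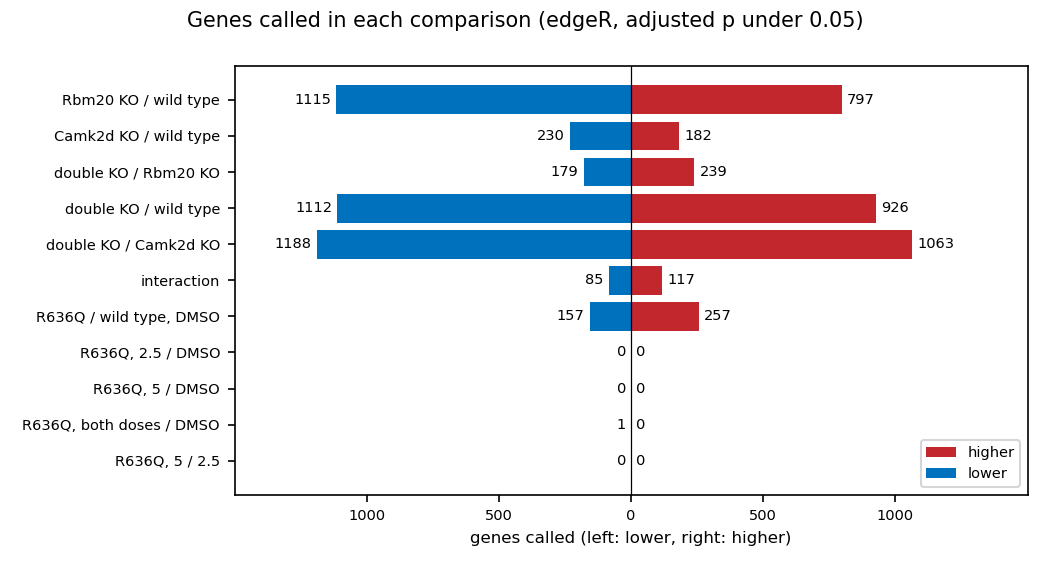
Numbers of genes called by edgeR at an adjusted p under 0.05 in each comparison. The horizontal axis counts genes, lower to the left and higher to the right. The Rbm20 knockout gave 1115 falls and 797 rises, R636Q hearts 157 and 257, and hesperadin 1 call with both doses together.

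Libraries labelled Camk2d knockout showed fewer changes against wild type, with less haemoglobin transcript. Of 14077 genes 182 rose and 230 fell, 40 and 48 of them at least 2-fold. Other tools called more, with 620 genes by DESeq2 and 637 by voom. Leaving out 1 library gave 201 (wild-type library 5), 206, 220 and 249 (libraries 1, 3 and 4 labelled Camk2d knockout) and 265 (wild-type library 1). The largest rises were those of Nxpe4 (4.84 ± 0.90), the lipid transporter Abca4 (3.28 ± 0.44), Kbtbd13 (2.28), the desaturase Scd4 (2.28), Klhl32 (1.89), nicotinamide N-methyltransferase Nnmt (1.72), Alpk1 (1.34), the chloride channel Clcn1 (1.32), calpain 3 (Capn3, 1.28) and the cytokine signalling suppressor Socs2 (1.23). Olfr1033 (-6.93 ± 1.58), Egf (-2.40), Cnmd (-2.17), Amd2 (-2.02), Cd300ld3 (-1.99), Hba-a1 (-1.83), Ang (-1.79), Nr4a1 (-1.76), Hbb-bt (-1.59) and S1pr5 (-1.57) fell most. Hba-a1 and Amd2 have near-identical copies, and reads may be divided among copies in ways the counting does not show. Leaving out single libraries ended the calls of Klhl32, Clcn1, Socs2, Olfr1033, Cnmd, Amd2, Hba-a1 and Nr4a1, with adjusted p up to 0.111 for Klhl32 without wild-type library 5. Abca4, Egf and Alpk1 lie within 20 Mb of Camk2d on chromosome 3, and so did more called genes than elsewhere: 12 of 175 tested genes between 1 and 20 Mb from Camk2d (6.86%) against 2.86% of genes elsewhere (Fisher's exact test, two-sided p = 0.00524). Egf was not particular to the Camk2d knockout label, since it also fell in the Rbm20 knockout, as given above. Between the double knockout label and Rbm20 knockout it differed by 0.0578, without a call.

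Of 6 erythroid markers 4 fell in libraries labelled Camk2d knockout (5 adjusted over the list alone). Haemoglobin beta Hbb-bs stood at 892 ± 156 CPM in wild type and 316 ± 38.2 CPM with the label (log2 fold change -1.49 ± 0.25), and Alas2, the erythroid heme synthesis enzyme, fell by 1.47 on the log2 scale. The list passed camera (adjusted p 3.92e-13) and held with an estimated correlation (adjusted p = 0.0161). Of 17 immediate early genes 2 fell (7 adjusted over the list alone, camera adjusted p 1.14e-05, 0.515 with an estimated correlation), the nuclear receptors Nr4a3 (-1.40) and Nr4a1, which was at 11.4 ± 4.69 and 3.34 ± 0.74 CPM. Among 15 fetal and stress genes 1 fell, Ankrd1 (1 up and 5 down adjusted over the list alone), a stretch-responsive cofactor, from 2041 ± 125 to 1010 ± 225 CPM (-1.01 ± 0.17). That list passed camera (adjusted p 3.65e-05) but not with an estimated correlation (adjusted p = 0.388). Atrial markers were uneven beside it: Myl7 stood at 70.5 CPM in library 2 with this label and at 11.1 CPM in wild-type library 5, and at or below 1.96 CPM in the other libraries of both groups, and without all libraries over 10 CPM the comparison called 225 genes. Of 21 fatty acid oxidation genes 2 rose (8 up and 1 down adjusted over the list alone, camera adjusted p 1.43e-06, 0.592 with an estimated correlation), Mlycd (0.43) and Slc25a20 (0.35). Of 23 RBM20 splicing targets 3 fell (5 adjusted over the list alone, camera adjusted p 0.00107, 0.592 with an estimated correlation), Sorbs1 (-0.50), Dtna (-0.27) and Mlip (-0.30). All 5 of these calls ended without single libraries, with adjusted p up to 0.0817 for Mlip without library 1 of this label. The mitochondrially encoded list (0 of 13 called, camera adjusted p 0.0151) and the glycolysis list (0 of 17, 0.0421) leaned down, and neither passed with an estimated correlation (adjusted p = 0.802 for each). The remaining lists did not pass camera.

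The comparison of the double knockout label with the Rbm20 knockout asks what the Camk2d knockout, by its label, changes in Rbm20 knockout hearts. It gave 239 rises and 179 falls, 73 and 30 of them at least 2-fold. Cyfip2 rose from 3.65 ± 1.08 to 56.6 ± 17.8 CPM (log2 fold change 3.95 ± 0.24) and Abca4 from 0.216 ± 0.088 to 4.27 ± 0.50 CPM (4.27 ± 0.51). Phenylalanine hydroxylase Pah (5.67 ± 1.43), securin Pttg1 (4.14), the cardiac kinase Tnni3k (2.98), Gpnmb (2.67), Ifi205 (2.63), the protease inhibitors Timp4 (2.21) and Serpina3n (1.99) and Mt2 (1.62) also rose. The falls were smaller: Prnd (-1.74), Apol10b (-1.68), the acyl-CoA synthetase Acsl6 (-1.52), Col22a1 (-1.48), Cdh20 (-1.28), Emilin2 (-1.24), the chemokine receptor Cx3cr1 (-1.22), Cdh4 (-1.22), Lrtm1 (-1.04) and the apelin receptor Aplnr (-1.02). Leaving out single libraries ended the calls of Pah, Apol10b, Cdh20 and Cdh4, with adjusted p up to 0.122 for Cdh4 without Rbm20 knockout library 4. The count fell to 241 and 247 without Rbm20 knockout library 3 or 4, and to 262 in a fit of these 2 groups alone. Of genes between 1 and 20 Mb from Camk2d, 21 of 175 were called (12%) against 2.84% elsewhere (Fisher's exact test, two-sided p = 5.05e-08), Abca4 among them.

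Of 21 fatty acid oxidation genes 5 rose with the double knockout label against Rbm20 knockout and 0 fell (8 and 0 adjusted over the list alone), among them the carnitine carrier Slc25a20 (0.43 ± 0.083), Acot2 (0.49), the fatty acid transporter Cd36 (0.29) and uncoupling protein Ucp3 (1.15). That list passed camera (adjusted p 3.2e-08) but not with an estimated correlation (adjusted p = 0.633). Of 14 p53 target genes 2 rose (4 adjusted over the list alone, camera adjusted p 0.019, 0.633 with an estimated correlation), Fas (0.76) and Cdkn1a (0.94). Of 12 endothelial markers 1 rose, Flt1 (0.32), and 1 fell, Emcn (-0.33), with a camera adjusted p of 0.0433 and of 0.633 with an estimated correlation. Of 15 interferon response genes 1 fell, Stat1 (-0.51), with a camera adjusted p of 0.000337 and of 0.633 with an estimated correlation. Acot2, Cd36, Ucp3, Fas, Cdkn1a, Flt1, Emcn and Stat1 each lost the call without single libraries, with adjusted p up to 0.122 for Cdkn1a without Rbm20 knockout library 4. The nuclear OXPHOS list leaned up with 0 of 28 members called (camera adjusted p 0.00363, 0.775 with an estimated correlation). Among 15 fetal and stress genes 0 were called (4 up and 1 down adjusted over the list alone), and the list leaned up (camera adjusted p 0.0189, 0.633 with an estimated correlation). Fhl1 differed by 0.47 with an adjusted p of 0.0506 and Nppa was at 1516 ± 473 against 1101 ± 483 CPM without a call. Beside this, the atrial gene Myl7 stood at 183 CPM in double knockout library 5 and 16.2 CPM in library 4, and at or below 9.16 CPM in every Rbm20 knockout library. The remaining lists did not pass camera.

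Against wild type, hearts labelled double knockout had more transcript of fetal and stress genes. Matrix, ion channel and fuel lists passed camera but not with an estimated correlation, where the lowest adjusted p = 0.288, for glycolysis. The comparison called 926 rises and 1112 falls. Nppa rose from 139 ± 27 to 1516 ± 473 CPM (3.44 ± 0.35), with 2340 CPM in library 1 and 1190 to 1460 in the others, after Ces5a (4.78), AW551984 (4.05), Adamts20 (3.73), Serpinb1c (3.69), St8sia1 (3.69), Dusp26 (3.68), the cobalamin receptor Cubn (3.60) and Syndig1 (3.54). Selenbp2, at 1.9 ± 0.80 CPM in wild type, had 0 counts in all 5 double knockout libraries, so it was at least 74.1-fold lower (floor of 3 counts over the group). Aldob (-4.14), Ptchd3 (-4.03), the calcium channel subunit Cacng6 (-3.48), Rtn4r (-2.57), Egf (-2.54), Stum (-2.19), the sodium channel Scn10a (-2.18) and Acsm5 (-2.09) fell. Of 15 fetal and stress genes 11 rose (13 adjusted over the list alone), and the list passed camera (adjusted p 6.1e-20) and held with an estimated correlation (adjusted p = 0.00522). Fhl1 reached 231 ± 49 CPM, with 318 in double knockout library 3 and 206 to 212 in the others, and Xirp2 1204 ± 264 CPM. Of 7 atrial markers 1 rose, Nppa, and 1 fell (camera adjusted p 0.117), with Myl7 uneven as above. Extracellular matrix genes had 8 rises (12 adjusted over the list alone, camera adjusted p 1.09e-07, 0.568 with an estimated correlation), with Tgfb2 at 1.37 and Timp1 at 1.52. Cardiac ion channels had 2 rises and 6 falls (2 and 7 adjusted over the list alone, camera adjusted p 0.0228, 0.568 with an estimated correlation), with Hcn2 at 4.83 ± 1.10 CPM (-1.59), Kcnd2 at 4.68 ± 1.94 CPM against 14.9 ± 2.71 in wild type (-1.67), Kcnip2 at -0.72 and Scn4b at -1.69. Among fuel genes, 7 of 21 fatty acid oxidation genes fell (1 up and 12 down adjusted over the list alone), 12 of 28 nuclear OXPHOS genes (1 and 15) and 10 of 17 glycolysis genes (1 and 13). The camera adjusted p was 0.00147, 4.17e-05 and 8.49e-07 for these lists, and with an estimated correlation the adjusted p = 0.814, 0.667 and 0.288. Sarcomere (camera adjusted p 0.0228), circadian clock (0.026) and fibroblast (0.00182) lists also passed upwards and the erythroid list (0.0175) downwards, and none of them with an estimated correlation, where adjusted p = 0.814, 0.288, 0.568 and 0.568.

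The Rbm20 effect was also seen between both groups with the Camk2d knockout label. The double knockout label against the Camk2d knockout label gave 1063 rises and 1188 falls. Of 15 fetal and stress genes 12 rose (13 adjusted over the list alone), with Ankrd1 from 1010 ± 225 to 4468 ± 1394 CPM (2.14 ± 0.17), the actin regulator Enah (1.03), Fhl1 (1.54) and Xirp2 (1.88). The list passed camera (adjusted p 1.28e-31) and held with an estimated correlation (adjusted p = 0.000376). Myl7 was over 10 CPM in 2 libraries of the double knockout label and 1 of the Camk2d knockout label. Cardiac ion channels had 1 rise and 9 falls (1 and 10 adjusted over the list alone, camera adjusted p 0.000212, 0.33 with an estimated correlation), with Hcn2 at -1.56 and Kcnh2 at -0.57. Of 17 immediate early genes 6 rose (6 adjusted over the list alone, camera adjusted p 0.0116, 0.716 with an estimated correlation), such as Nr4a1 (2.05) and Atf3 (1.71). Fatty acid oxidation genes had 15 falls of 21 (16 adjusted over the list alone, camera adjusted p 1.24e-11, 0.33 with an estimated correlation) and sarcomere genes 9 rises of 23 (11 up and 2 down adjusted over the list alone, camera adjusted p 0.000208, 0.559 with an estimated correlation). Extracellular matrix (4.2e-07) and fibroblast (0.00216) lists and the erythroid list (0.0324) passed camera upwards, and nuclear OXPHOS (3.41e-07) and glycolysis (0.00227) lists downwards. With an estimated correlation their adjusted p = 0.559, 0.559, 0.602, 0.559 and 0.559. The largest single changes were Ces5a (5.08), Syndig1 (5.02), Serpinb1c (4.82) and Vgll2 (4.02) upwards and Ptchd3 (-4.56), Aldob (-4.07) and Cacng6 (-4.04) downwards.

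**Figure D3:**
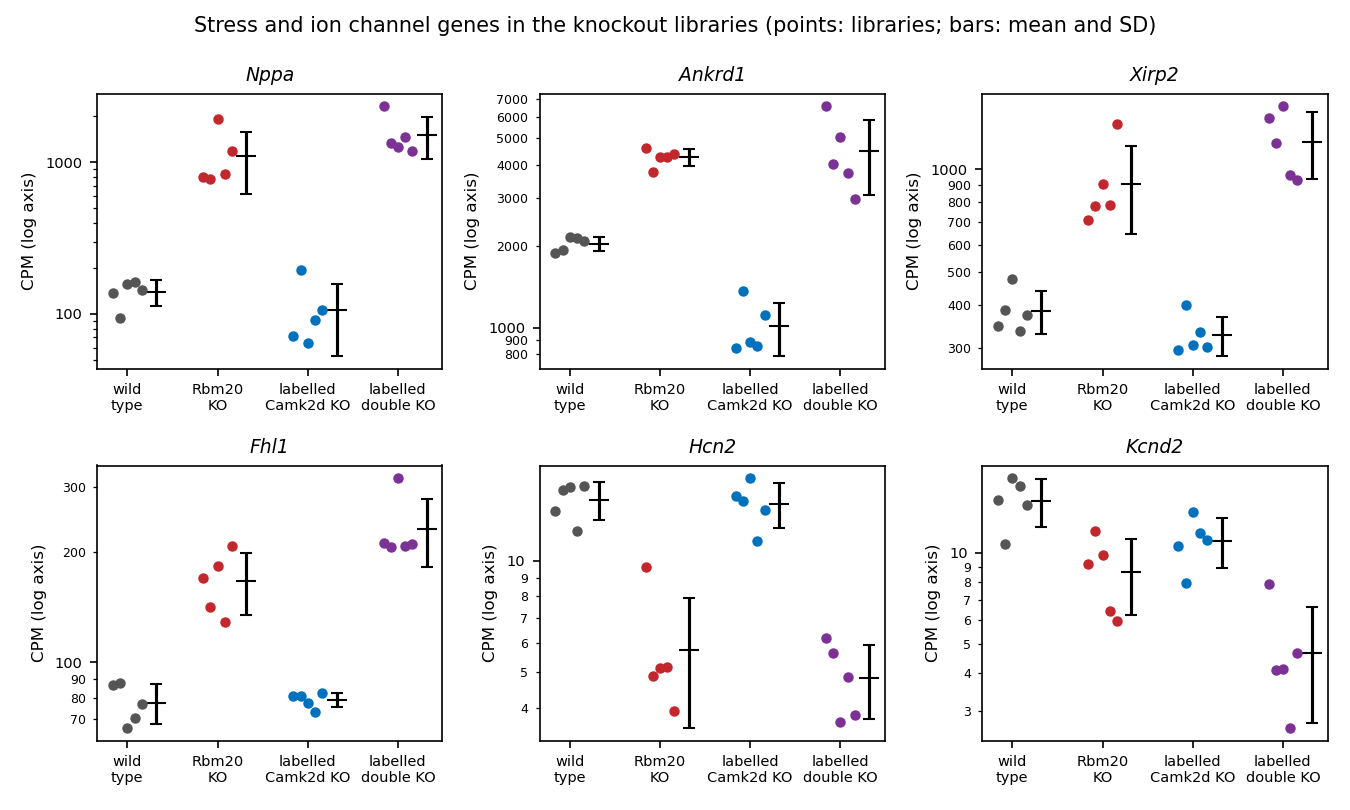
CPM on log axes of Nppa, Ankrd1, Xirp2, Fhl1, Hcn2 and Kcnd2 in the 20 knockout libraries, by group. Points are libraries and bars give mean and SD. Nppa averaged 139 CPM in wild type, 1101 in the Rbm20 knockout, 105 with the Camk2d knockout label and 1516 with the double knockout label, while Hcn2 averaged 14.6, 5.74, 14.2 and 4.83 CPM.

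The interaction tests whether the change with the Camk2d knockout label differed between Rbm20 knockouts and mice with intact Rbm20. It called 117 genes upwards and 85 downwards. Cyfip2 had the largest positive difference (4.99 ± 0.31), since it was lower with the label in mice with intact Rbm20 (58.9 ± 2.90 against 121 ± 24 CPM) and higher in Rbm20 knockouts. It was followed by Pttg1 (4.14), Amd2 (3.61), Hba-a2 (3.55), Ifi205 (3.43), Arrdc2 (2.60), Mt2 (2.48), Egf (2.45), Nr4a1 (2.36) and Serpina3n (2.21). The largest negative differences were those of Nxpe4 (-5.17 ± 1.13), Kbtbd13 (-3.03), Prnd (-1.97), Acsm5 (-1.93), Gsta1 (-1.91), Ddc (-1.79), Oas1a (-1.75), Emilin2 (-1.56), Mycn (-1.56) and the peptide hormone apelin Apln (-1.53). Of 15 fetal and stress genes 2 were called upwards (9 adjusted over the list alone, camera adjusted p 7.74e-08, 0.115 with an estimated correlation), Ankrd1 (1.09 ± 0.23) and Ccn2 (1.80). Of 6 erythroid markers 2 were called upwards (5 adjusted over the list alone, camera adjusted p 2.17e-08, 0.114 with an estimated correlation), Hba-a2 and Alas2 (1.60). The immediate early list passed camera upwards (0.00019) and the interferon response (8.66e-06), cardiac ion channel (0.00999) and endothelial (0.00421) lists downwards, each with adjusted p = 0.434 with an estimated correlation. The count was 406 with DESeq2, and it fell to 77 and 128 without Rbm20 knockout libraries 4 and 1, to 121, 85, 120 and 120 without libraries 1, 3, 4 and 5 of the Camk2d knockout label, to 126 without double knockout library 4, and to 123 and 102 without wild-type libraries 2 and 5. Calls of Pttg1, Hba-a2, Nr4a1, Nxpe4, Prnd, Gsta1, Oas1a, Ankrd1, Ccn2 and Alas2 ended without single libraries, with adjusted p up to 0.101 for Oas1a without library 3 of the Camk2d knockout label.

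How far the double knockout label went back towards wild type was asked of the 1912 genes called in the Rbm20 knockout. Of these, 151 were called the opposite way between the double knockout label and Rbm20 knockout, 105 of them back up and 46 back down, and 15 were called further the same way. Independent lists of these sizes would share 18.9 and 10.1 genes in the opposite directions and 27.7 in the same direction. Both comparisons hold the Rbm20 knockout libraries. Simulated unchanged groups gave 0 opposite calls in 20 simulations. In these the double knockout was like the Rbm20 knockout, so hardly any gene could be called between them. The 0 calls therefore do not show how far the shared libraries add opposite calls where the groups differ. With those libraries divided between the comparisons, the median over 20 divisions was 33 opposite calls (15 to 51) and 5.5 in the same direction (1 to 29). Over all 1912 genes 69.3% had opposite signs, against 64.2% in simulations where the double knockout was like the Rbm20 knockout, and the covariance of the fold changes was -0.0893 against -0.0291. With the Rbm20 knockout libraries divided, the median share of opposite signs was 63.4% (43.9 to 72.5%). Without Rbm20 knockout library 3 or 4 the opposite calls were 90 or 94. Cyfip2 led them (-5.05, then 3.95), before Osbpl3 (0.40, then -0.87), Lyrm7 (-0.53, then 0.86), the lysosomal mannosidase Manba (-0.74, then 0.80), the ribosomal protein gene Rpl34 (-0.63, then 0.69) and Tuba1c (-1.16, then 0.83). These genes are ranked by their adjusted p with the double knockout label and were picked after their values were seen. Manba and Rpl34 lie within 20 Mb of Camk2d. Of the 151, Pla2g12a, Mcub, Ostc, Hadh, Abcd3, S1pr1, Dnajb14, Adh5 and Ddah1, named outside the rule, lie there too. On chromosome 11, where Cyfip2 lies, were 24 of the 151 opposite calls (Fisher's exact test, two-sided, adjusted p 0.028 over the chromosomes). Of the 1912 genes 1107 were still called in the same direction with the double knockout label against wild type and 2 in the other, and 13 of the 151 were still called against wild type. The 151 were chosen for moving back, so few calls against wild type follow in part from that choice. A missing call does not show a return to the wild-type level. Osbpl3 (-0.48) and Lyrm7 (0.32) were called against wild type in the direction opposite to the Rbm20 knockout.

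In heterozygous R636Q hearts on DMSO, stress and atrial peptide transcript rose and Myh7b was nearly lost. Of 14579 genes 257 rose and 157 fell against wild type on DMSO, 87 and 46 of them at least 2-fold. Over all 14579 genes, the 3 libraries of each group did not overlap in 2700, where chance gives 10% of genes. Library measures separated the groups too: ribosomal RNA genes took 2.45 to 3.31% of counts in wild type and 1.57 to 2.41% in knock-in libraries on DMSO, and the ratio of Ttn to Myh6 counts was 1.14 to 1.33 and 1.54 to 2.23. In the knockout set this ratio was 0.146 to 0.182 in wild type and 0.204 to 0.255 in the Rbm20 knockout. It was 0.126 to 0.139 with the Camk2d knockout label and 0.182 to 0.228 with the double knockout label. The ratio thus went with altered Rbm20 in both sets. Without ribosomal RNA genes 416 genes were called. Nppa rose from 127 ± 16.6 to 888 ± 159 CPM (n = 3 each), a log2 fold change of 2.81 ± 0.19. The pacemaker channel Hcn1 (4.43 ± 0.73), Casq1 (3.99 ± 0.31), Prom2 (3.54), the kinase Rps6ka6 (3.37), the fast skeletal troponin I Tnni2 (3.30), the calcium pump Atp2b3 (3.07), Sv2b (2.30), Grin2c (2.30) and Ccl21e (2.30) were the other large rises. Myh7b, a myosin heavy chain gene, fell from 184 ± 25.5 to 2.34 ± 0.63 CPM (-6.30 ± 0.21). Strit1, which encodes a small activator of the calcium pump, was at 2.27 ± 1.28 CPM in wild type and had 0 counts in all 3 knock-in libraries, at least 40.3-fold lower. Rgs13 was likewise at least 20.4-fold lower. Rgs1 (-4.24), Aldob (-4.00), Ubxn10 (-3.87), the homeodomain-only protein Hopx (-3.86), the water channel Aqp4 (-3.46), Pde11a (-3.28) and Csrnp3 (-3.08) fell. DESeq2 called 662 genes, a fit of these 2 groups alone 246, and leaving out wild-type library 2 gave 221. Single libraries ended the calls of Hcn1, Prom2, Atp2b3, Ccl21e and Csrnp3, with adjusted p up to 0.176 for Csrnp3 without wild-type library 2.

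Of 15 fetal and stress genes 2 rose in R636Q hearts (3 up and 1 down adjusted over the list alone), Nppa and Enah (0.60 ± 0.098). The list passed camera (adjusted p 5.79e-06) and held with an estimated correlation (adjusted p = 0.0184). Ankrd1 differed by 1.66 ± 0.40 (adjusted p 0.0775). The 4 atrial markers also passed (camera adjusted p 2.65e-05, 0.0207 with an estimated correlation), with Nppa and Dkk3 (1.55) called (2 up and 1 down adjusted over the list alone) and the atrial myosin light chain Myl4 at 0.06 ± 0.31. Among 21 cardiac ion channel genes 3 rose and 1 fell (3 and 3 adjusted over the list alone, camera adjusted p 0.108): Hcn2 from 16.8 ± 2.72 to 55 ± 11.1 CPM (1.71), the T-type calcium channels Cacna1h (2.12) and Cacna1g (1.18), and Kcnd2 (-1.06). Of 21 fatty acid oxidation genes 2 fell (9 adjusted over the list alone, camera adjusted p 1.4e-06, 0.354 with an estimated correlation), Etfb (-0.35) and Decr1 (-0.45). Of 27 extracellular matrix genes 2 rose (2 adjusted over the list alone, camera adjusted p 0.000329, 0.678 with an estimated correlation), Sparc (0.80) and Mfap4 (2.00). Of 28 nuclear OXPHOS genes 1 fell, Cox8b (-0.41), with a camera adjusted p of 0.00435 and of 0.678 with an estimated correlation. Of 14 integrated stress response genes 2 rose (2 adjusted over the list alone, camera adjusted p 0.00554, 0.678 with an estimated correlation), Aldh1l2 (0.86) and the transcription factor Atf4 (0.53). The interferon response list leaned up with 0 of 16 called (camera adjusted p 0.00554, 0.883 with an estimated correlation). Dkk3, Cacna1g, Kcnd2, Etfb, Decr1 and Cox8b lost their calls without single libraries, with adjusted p up to 0.169 for Dkk3 without wild-type library 2. The wild-type libraries on DMSO were all low in Xist, an RNA of the inactive X chromosome, and 1 of 3 knock-in libraries on DMSO was high in it. With Xist as a covariate 378 genes were called.

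Both models shared part of their changes. The genes called in the Rbm20 knockout, 1765 of them measured in the hesperadin set, moved in R636Q hearts with the same sign in 67.9%, and these comparisons share no libraries. Limma's fry gave a directional p = 0.002, while the exact permutation of the 6 libraries has 10 splits, too few for a p under 0.05. The signed mean was 0.147 on the log2 scale in the real split and at most 0.115 in the others. Among 148 genes called in both, 119 had the same direction. These included Nppa, Aldob, Casq1, Mfap4 (1.71 in the Rbm20 knockout), Kcnd2 (-0.79), Cacna1g and, of genes picked after their values were seen, Mybpc2 (2.02 and 2.21 in R636Q hearts) and Angptl4 (-1.50 and -2.20). The other 29 were called in opposite directions, among them Hcn2, which fell in the Rbm20 knockout and rose in R636Q hearts, and Myh7b (0.42 and -6.30). Of the latter kind, Cubn (2.40 and -1.68), Tmprss13 (-3.02 and 1.77) and the sodium channel subunit Scn1b (-0.33 and 0.83) were picked after their values were seen.

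Hesperadin changed few genes in R636Q hearts by these tests. At 2.5 ug/mg edgeR called 0 of 14579 genes, with 421 at an unadjusted p under 0.05 where chance gives 729, and a smallest adjusted p of 0.237. DESeq2 called 3 and voom 0. At 5 ug/mg edgeR called 0 genes, with 1205 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0704. DESeq2 called 44 and voom 0. A fit with the replicate number as a block called 7, and leaving out knock-in DMSO library 3 gave 13 calls. Between the doses edgeR called 0 genes (661 at an unadjusted p under 0.05, DESeq2 2, voom 0). With both doses together 1 gene was called, glucokinase Gck (chromosome 11, 5900820 to 5950081, minus strand), the hexokinase of liver and pancreatic islets. Gck stood at 10.5 to 17.6 CPM in knock-in libraries on DMSO, at 2.08 to 4.37 CPM in the 6 treated ones and at 13.2 to 26.1 CPM in wild type (log2 fold change -2.26 ± 0.25, adjusted p 0.013). It was lower in 6 of 6 treated libraries, but Gck was picked by its p. Over all 14579 genes the treated and DMSO knock-in libraries did not overlap in 311, where chance gives 2.38% of genes. The call ended without knock-in DMSO library 2, any 5 ug/mg library or 2.5 ug/mg library 1, with adjusted p up to 0.119. It also ended with Xist as a covariate (-2.16, adjusted p 0.121) and with voom (-2.25, adjusted p 0.0869). Leaving out knock-in DMSO library 3 gave 10 calls, as many as DESeq2. The libraries also differed in the clock gene Bmal1, between 2.6 and 3.94 CPM in knock-in DMSO libraries 1 and 2 and 2.5 ug/mg libraries 1 and 2, and between 13.5 and 22 CPM in knock-in DMSO library 3 and the other treated ones.

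The fetal and stress list leaned down with hesperadin although 0 of its 15 members were called. The camera adjusted p was 0.000749 at 2.5 ug/mg, 0.0284 at 5 ug/mg and 0.000519 for both doses together, and with an estimated correlation the adjusted p = 0.0586, 0.197 and 0.0522. Adjusted over the list alone, 1, 2 and 2 members fell. Nppa was at 707 to 1000 CPM in the knock-in libraries on DMSO and 436 to 758 in the treated ones, with log2 fold changes of -0.40 ± 0.18 and -0.72 ± 0.18 at the lower and higher dose and no call. Xirp2 was at 2700 ± 529, 2020 ± 70 and 1780 ± 164 CPM (-0.42 and -0.60, not called). At 2.5 ug/mg the immediate early list leaned up (camera adjusted p 0.0386) and the ER chaperone (0.0309), macrophage (0.0386) and erythroid (0.0339) lists down, each with adjusted p = 0.83 with an estimated correlation. At 5 ug/mg the cardiac ion channel list leaned up (0.0389) and the circadian clock list down (0.0389), with adjusted p = 0.197 and 0.756 with an estimated correlation. Hcn4 differed by 0.81 and Kcnj5 by 0.40 without a call. Between the doses camera passed 7 lists. At the higher dose the circadian clock (9.53e-05), immediate early (0.00138) and mitotic and Aurora kinase (0.00138) lists leaned down, and the extracellular matrix (0.00697), macrophage (0.00748), fibroblast (0.0102) and erythroid (0.0385) lists up, with 0 called members in each. None passed with an estimated correlation, where the lowest of the 7 was adjusted p = 0.399, for the clock list.

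**Figure D4:**
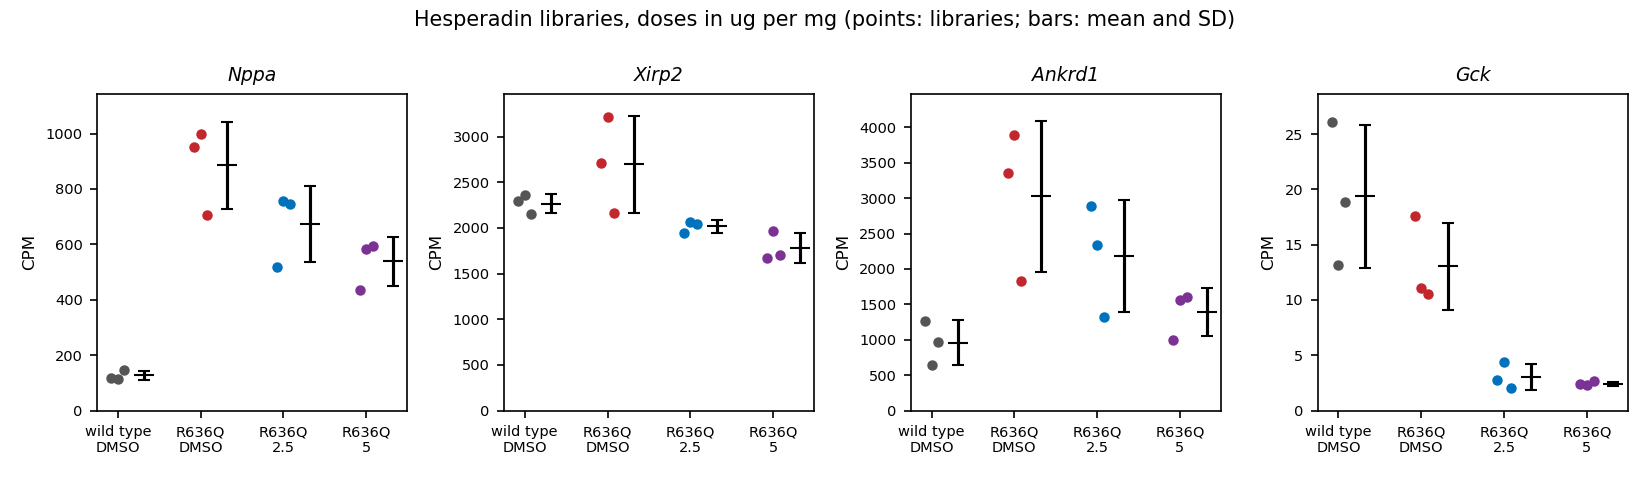
CPM of Nppa, Xirp2, Ankrd1 and Gck in the 12 hesperadin libraries, by group (doses in ug/mg). Points are libraries and bars give mean and SD. Gck lay between 2.08 and 4.37 CPM in the treated libraries and between 10.5 and 26.1 in the others.

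Of the 414 genes called in R636Q hearts, 0 were called the opposite way with hesperadin by edgeR at either dose or with both together (1 gene called in all). Opposite signs were seen in 68.6, 58.9 and 63.8% of them at the lower dose, the higher dose and both, against 67.2, 67.3 and 69.3% in simulations where treated hearts were like those on DMSO. The share at the lower dose lay within the range of those simulations (64.5 to 73.4%). Those at the higher dose and for both lay below the lowest simulation (63 and 64.3%), so no excess of opposite signs was seen. The knock-in DMSO libraries are shared by both comparisons, and too few to divide, so opposite signs may come in part from them. The covariance of the fold changes was -0.0356, -0.0349 and -0.0352, against -0.0387, -0.0388 and -0.0387 in those simulations. Without knock-in DMSO library 3 there were 3 opposite calls at the higher dose and 2 with both doses.

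Whether the inhibitor and the Camk2d knockout label move the same genes was asked with the genes called in the knockout set. The 381 measured genes called between the double knockout label and Rbm20 knockout had the same sign with hesperadin in 50.4, 48.6 and 53.3% at the lower dose, the higher dose and both (fry, adjusted p 0.854 for each over 6 tests). The 371 genes called with the Camk2d knockout label against wild type had the same sign in 64.4, 68.5 and 69.3% (fry, adjusted p 0.037, 0.00747 and 0.00747), with signed medians of 0.06, 0.09 and 0.08 on the log2 scale. Without wild-type library 3 of the knockout set the result ended at both doses and for both together (65.4, 60.8 and 64.2%, adjusted p 0.12, 0.0597 and 0.0597). At the lower dose it also ended without library 5 of the Camk2d knockout label (65%, adjusted p 0.078), knock-in DMSO library 1 (59.8%, 0.136) or 2 (63.4%, 0.113), or 2.5 ug/mg library 1 (64.4%, 0.0758) or 3 (58.5%, 0.131).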

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

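Tests chosen only after their results were seen are those of the nearest neighbours of Camk2d, of Capza1 with its pseudogene, of clock genes as a covariate and of simulated power. The fit with Xist was planned, and its use to test why few genes were called with hesperadin was chosen afterwards. Of 80 groups of 5 libraries checked for a library far from the others, 8 passed a gap of 0.71 of the group's range, and chance gives 4. The gap was 0.77 for Nppa with the double knockout label (library 1 at 2340 CPM, the others 1190 to 1460), 0.945 for Fhl1 with that label (library 3 at 318 CPM, the others 206 to 212), and 0.778 for Hcn2 in the Rbm20 knockout (library 1 at 9.58 CPM, the others 3.92 to 5.17). In wild type it was 0.807 for Cyfip2 (library 5 at 78.8 CPM, the others 127 to 139) and 0.758 for Capza1 (library 3 at 10.5 CPM, the others 9.21 to 9.51). It was 0.898 for total counts in the Rbm20 knockout (library 4 at 23600000, the others 22500000 to 22700000), 0.756 for the mitochondrially encoded share there (library 5 at 44.7%, the others 49.7 to 51.3%) and 0.727 for the ratio of Ttn to Myh6 counts with the Camk2d knockout label (library 5 at 0.126, the others 0.136 to 0.139). No explanation of these libraries was tested.

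The change with the Camk2d knockout label differed between mice with intact Rbm20 and Rbm20 knockouts, by the interaction test, for these genes. Cyfip2 changed by -1.04 with intact Rbm20 and by 3.95 in Rbm20 knockouts, a difference of 4.99 on the log2 scale (edgeR adjusted p 4.55e-08). The difference was 4.14 for Pttg1 (adjusted p 0.0419), 3.61 for Amd2 (0.0137), 3.55 for Hba-a2 (0.0459), 3.43 for Ifi205 (0.00877), 2.36 for Nr4a1 (0.0379) and 1.09 for Ankrd1 (0.0251). It was -5.17 for Nxpe4 (0.0334), -3.03 for Kbtbd13 (0.0219), -1.97 for Prnd (0.0296), -1.93 for Acsm5 (0.00483) and -1.91 for Gsta1 (0.0385). The calls of Pttg1, Hba-a2, Nr4a1, Ankrd1, Nxpe4, Prnd and Gsta1 ended without single libraries, with adjusted p up to 0.0906 for Hba-a2 without Rbm20 knockout library 4. Of 100 splits of the libraries the real one gave the most interaction calls, 202 against 4 in the highest other. These splits shuffled the labels of all groups and so also broke up the Rbm20 difference. They therefore cannot exclude chance for the interaction count alone. Whether a difference in strain background between the lines accounts for Cyfip2, on chromosome 11, was not tested and stays open.

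Genes called between libraries with and without the Camk2d knockout label lay near Camk2d on chromosome 3. In the comparison of the Camk2d knockout label with wild type 12 of 175 genes from 1 to 20 Mb away were called, 2.39 times the share elsewhere (Fisher's exact test, two-sided p = 0.00524), and 21 of 175 with the double knockout label against Rbm20 knockout (p = 5.05e-08, Fisher's exact test). This argues against an effect of the deletion on its nearest neighbours alone. A chromosome segment or strain variant carried with the Camk2d allele may account for a part of the calls. Of the 12 genes, 75% had the same sign in the other pair of groups (9 of 12), but so did 66.3% of called genes elsewhere (Fisher's exact test, two-sided p = 0.758). The segment and an effect of the kinase both predict the same sign, so this share cannot tell them apart. Only 3 genes there were called in both pairs of groups, all with the same sign. Others, such as Rpl34 and Adh5, were called in the Rbm20 knockout against wild type (-0.626 and -0.379). They hardly differed between the Camk2d knockout label and wild type (0.062 and 0.0445). In these genes the Rbm20 knockout was the group set apart. Capza1, also on chromosome 3, was at 9.59 ± 0.50 CPM in wild type, 18.9 ± 1.26 with the Camk2d knockout label and 27.7 ± 0.97 with the double knockout label (SD, n = 5), while its pseudogene was at 10.6 ± 1.36, 6.01 ± 0.84 and 0.0792 ± 0.075 CPM. The log2 ratio of their summed CPM between the Camk2d knockout label and wild type was 0.303, which leaves open how far reads were shared between them. An effect of the kinase on genes wherever they lie would give no higher called share near Camk2d than elsewhere. The shares were 6.86% against 2.86% for the Camk2d knockout label against wild type. They were 12% against 2.84% for the double knockout label against Rbm20 knockout. In the Rbm20 knockout against wild type they were 17.1% and 13.5% (Fisher's exact test, two-sided p = 0.182). Between the groups labelled double and Camk2d knockout they were 14.9% and 16% (Fisher's exact test, two-sided p = 0.756). This argues against such an effect as the cause of the excess near Camk2d, while its part in single genes there was not tested.

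The Camk2d count differed by -0.18 on the log2 scale with the Camk2d knockout label, without a call. Among Rbm20 knockout and double knockout libraries, mislabelling is argued against by the genes within 20 Mb of Camk2d that were called with the Camk2d knockout label against wild type: 10 of 10 of these libraries, which had no part in that choice, lay on the side of their label. The Camk2d knockout and wild-type libraries served to choose the genes, so their own labels could not be tested this way. Nor does this show that the knockout allele is present in a library. Counts in the knockout table that do not scale with transcript length, as those of tags from one part of a transcript would, are a candidate explanation. The log2 ratio of CPM between the knockout and hesperadin tables had a slope of -0.637 on log2 transcript length across 12594 genes (-0.655 to -0.619), where genes are not independent replicates. A count made from one part of Camk2d need not cover what was deleted, and the deleted part is not in the labels.

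Few genes were called with hesperadin. With Xist as a covariate 0 genes were called at the higher dose (edgeR, 0 without it, with 1205 genes at an unadjusted p under 0.05 and 44 called by DESeq2). A count of 0 in both fits cannot decide on mixed sexes, since few libraries were compared and the covariate takes up a residual degree of freedom. At the higher dose a clock gene covariate gave 1 call, which for the same reason does not decide on clock phase. With that covariate 4 genes were called at the lower dose (0 without it) and 614 in R636Q hearts on DMSO (414 without it), so a part of the clock in the counts stays open. The number of libraries may limit the calls: in simulated counts of this comparison 44.8% of genes set to change 1.5-fold were recovered, which leaves changes of that size open. A true lack of larger changes, the biological explanation, stays open too.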

How the results depend on the processing

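The alternatives chosen only after the data were seen are the clock gene covariate, leaving out libraries with Myl7 over 10 CPM and leaving out genes within 20 Mb of Camk2d or Rbm20. No called gene of the naming rule changed sign under the alternatives run for single genes, but calls were lost. Without libraries with Myl7 over 10 CPM, 15 of 77 were lost for the double knockout label against wild type, 10 of 76 against the Camk2d knockout label and 11 of 30 against Rbm20 knockout, 9 of 29 with the Camk2d knockout label against wild type, 9 of 24 in the interaction and 3 of 66 in the Rbm20 knockout. Without a low-count filter 8 of 24 were lost in the interaction, and at most 6 in each other comparison. A fit of only the 2 groups compared lost 7 of 33 in R636Q hearts, 9 of 76 for the double knockout label against wild type and at most 6 elsewhere. Voom lost at most 6 in a comparison, and DESeq2 1 in all. Lists changed direction with the replicate block only where they passed camera in neither fit, as the RBM20 splicing targets in the Rbm20 knockout did. Same-sign shares of genes called between the double knockout label and Rbm20 knockout crossed 50%, with 46.7 to 53.8% at the lower and 44.4 to 53.3% at the higher dose of hesperadin when single libraries were left out. For the double knockout label against the Camk2d knockout label, 1063 rises and 1188 falls became 829 and 793 without libraries with Myl7 over 10 CPM. Causes were not tested, except that fits of fewer libraries or groups had fewer to estimate the spread.

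DESeq2 called 620 genes (edgeR 412) with the Camk2d knockout label against wild type, 406 (202) in the interaction, 662 (414) in R636Q hearts, 3 (0) at the lower dose of hesperadin, 44 (0) at the higher dose, 10 (1) with both, and 2 (0) between doses. Voom called 637 genes with the Camk2d knockout label and 0 with both doses. A fit of only the 2 groups compared gave 262 for the double knockout label against Rbm20 knockout, 246 in R636Q hearts and 1 at the higher dose. Xist as a covariate gave 0 calls with both doses, and the clock gene covariate 4 and 1 at the lower and higher dose. Without libraries with Myl7 over 10 CPM 225 genes were called with the Camk2d knockout label against wild type.

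Leaving out each library in turn gave 201 to 378 calls with the Camk2d knockout label against wild type, 241 to 453 for the double knockout label against Rbm20 knockout, 77 to 215 in the interaction, 221 to 338 in R636Q hearts, 0 to 13 at the higher dose and 0 to 10 with both doses, and 0 to 0 at the lower dose and between doses. Opposite calls were 90 to 161 in the double knockout, 0 to 3 at the higher dose and 0 to 2 with both. The same-sign share of genes called with the Camk2d knockout label was 58.5 to 69.3% at the lower dose. The ranges were 1382 to 1958 calls in the Rbm20 knockout, and 1593 to 2134 and 1794 to 2108 for the double knockout label against wild type and against the Camk2d knockout label.

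Of 73 lists passed by camera over all comparisons, 6 passed with an estimated correlation and fry passed 34. Dividing the Rbm20 knockout libraries between both comparisons gave a median of 33 opposite calls, not 151, where each fit had fewer libraries.

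Replicate numbers were not taken to pair the libraries, since only 4 of 30 same-numbered pairs in the knockout set and 7 of 18 in the hesperadin set correlated above 0.1. Of the knockout libraries 3 of 20 correlated best with their own number. In the hesperadin set 8 of 12 did, with a median correlation of 0.0407 for the same number and -0.0167 for other pairs, which is a hint from the data, not the design, that some libraries of a number share something. With the replicate number as a block, 7 genes were called at the higher dose of hesperadin, and the counts were 329 with the Camk2d knockout label, 364 for the double knockout label against Rbm20 knockout, 136 in the interaction, where 9 of 24 named calls were lost, and 479 in R636Q hearts. Camera with the block also passed cardiac ion channels in R636Q hearts (adjusted p 0.0284), matrix genes at the higher dose (0.0318) and ER chaperones between doses (0.0202), all upwards. It no longer passed AhR and NRF2 targets in the Rbm20 knockout (0.0535). Depth limits genes of low counts: 14077 and 14579 genes passed the filter.

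Other splits of the libraries, 100 for each knockout comparison, exclude chance for the Rbm20 knockout (1912 calls, highest other 242) and the Camk2d knockout label (412, 6). They also do so for the double knockout label against Rbm20 knockout (418, 22), wild type (2038, 914) and the Camk2d knockout label (2251, 120). Opposite calls were 151 in the real split and at most 7 in the others. Those other splits called at most 22 genes in all, so they could not reach 151 and do not decide on the direction. Splits cannot tell the Camk2d knockout label from whatever else divides the same libraries, such as what their library numbers follow. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: R636Q hearts gave 414 (highest other 5), the lower dose 0 (5), the higher dose 0 (0) and the doses against each other 0 (0). For both doses 8 of 84 splits called as many genes as the real 1, so chance cannot be excluded. The highest other called 88 genes, with knock-in DMSO library 2, 5 ug/mg library 2 and 2.5 ug/mg library 3 on one side, which points to a structure of the samples.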

Other observations

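The test without immediate early, clock, erythroid and nearby genes was chosen before its result was seen, and the counts by chromosome were chosen after. The genes called with the Camk2d knockout label moved with hesperadin in the same direction more often than in opposite ones. Immediate early, clock and blood genes may account for this. Without these lists and the genes within 20 Mb of Camk2d, 350 genes were left, of which 68.6% had the same sign at the higher dose (68.5% of 371 with them). The listed genes alone therefore do not carry the share. Too few genes were taken out for the share to fall far, whatever their signs. The test could not decide on genes outside the lists that move with them. In R636Q hearts on DMSO against wild type 37.5% of the same genes had the same sign, and the knock-in DMSO libraries are part of both comparisons. Of 84 splits of the knock-in libraries 2, the real one among them, gave a signed mean as large as the real 0.111 for both doses (highest other 0.112). This share is under 0.05 but is not adjusted over the 6 tests of this kind. Another split of these libraries called 88 genes, so chance is not excluded. The same-sign result also ended at each dose without wild-type library 3 of the knockout set (fry, adjusted p 0.12 at the lower and 0.0597 at the higher dose). For the genes called in the Rbm20 knockout, the signed mean in R636Q hearts was 0.147 and the highest of the other splits 0.115, and 10 splits are too few for a share under 0.05.

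Of the 151 genes called in opposite directions in the Rbm20 knockout and with the double knockout label, 24 lay on chromosome 11, with 1145 tested genes (Fisher's exact test, two-sided p = 0.0014, adjusted p 0.028 over the chromosomes), and 13 on chromosome 3, with 679 tested genes (p = 0.052 by the same exact test, adjusted p 0.317). Chromosomes 3 and 11, picked after the data were seen, together held 24.5% of the 151 genes and 13% of tested genes. Most of those on chromosome 3 lay within 20 Mb of Camk2d. Whether the lines differ in strain background on these chromosomes was not tested.

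Myl7, Myl4 and Sln, which mark atrium, were uneven between libraries: Myl7 was at 183 CPM and Myl4 at 263 CPM in double knockout library 5, and at 70.5 and 95.9 CPM in library 2 with the Camk2d knockout label. Myl7 was at 0 CPM in double knockout libraries 1 and 3.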
